A study of Mus musculus with 2 samples.

How the data were processed

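RNA from 2 cultures of 46C mouse embryonic stem cells was compared, 1 library from cells with an empty vector (control) and 1 from cells that overexpressed ID2. Per the labels, the cells were at passages 21 to 24, RNA was extracted with Trizol, and libraries were made with a TruSeq RNA v2 kit, which does not mark the strand of origin. Per the submitters' processing notes, STAR, DESeq and the mouse genome build mm9 were used; versions, the gene annotation and the counting tool are not given in the sources used here.

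The deposited table held 14398 genes, each with a normalized signal value per library, the mean of both values, and the authors' own comparison. The fold deposited by the authors was the ratio of the ID2 value to the control value, and their log2 column was the log2 of that fold. The authors also deposited a p-value and an adjusted p-value per gene; recomputing the Benjamini-Hochberg adjustment over all 14398 genes gave the adjusted values with a largest relative difference of 0.0027. With 1 library per group, those p-values rest on a spread that was not measured between replicates, and they are quoted here only as the authors'.

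The deposited signal values were tested for traces of their processing. Every value was a whole number of steps, within 0.01 of a step, where 1 step was 0.995 in the control library and 1.00 in the ID2 library. Sorted from highest to lowest, the whole numbers of both libraries were identical, with 0 ranks that differed, and both summed to 25224015. Values of both libraries had therefore been set to a common distribution before a size factor was applied, a step for which no header or label gives a tool. The sequencing depth of each library is unknown for this reason, and no interval for counting error was computed. The authors' p-values were deposited beside these values and may rest on them rather than on read counts. In each library 10 genes shared the highest value, 117568 in the control library and 118714 in the ID2 library, so that ratios of genes at this ceiling are limited by it. The lowest mean was 14.0, and a gene that is not listed in the table cannot be given a level. Names of 20 rows read as dates, as spreadsheet programs write them, and 1 name occurred in 2 rows.

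The log2 ratio of ID2 to control was computed for each gene after adding a pseudocount of 1 to both values, which understates the ratio of low genes. Genes whose mean of both libraries was at least 50 were kept (12679 genes), and 1719 genes fell under this floor. A gene was counted as at least 2-fold apart by the size of its ratio alone. No test was run and no p-value of a group difference was computed, because a single library per group gives no spread between replicates. Counts of group members that were higher, lower or equal were taken on the whole numbers of steps, a choice made after seeing the data, since the size factors alone set equal numbers 0.01 apart on the log2 scale. A difference between these libraries is a difference between 2 cultures, whatever set them apart.

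For 31 gene lists holding 497 genes, the median log2 ratio of the members above the floor was set against 10000 random lists of the same size, matched on mean level in 20 bins. A list with at least 3 members was given a percentile, and a median below the 1st or above the 99th percentile is described as standing apart. This percentile describes these 2 libraries and is not a p-value, since genes are not replicates. The lists, the pseudocount, the floor, the 2-fold rule, the rule for named genes and the alternatives were chosen before the data were examined, apart from 3 alternatives that are identified with their results. The named genes were the 4 ID family genes, the 15 genes with the largest positive and the 15 with the largest negative log2 ratio above the floor (leaving out repeated, predicted and unnamed genes), up to 4 members of each list with the largest absolute ratio, and Pou5f1, Sox2 and Nanog. Genes named outside this rule are identified where they appear, and 3 genes that the rule names are not reported here.

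Alternatives were another scaling to a median ratio of 1, the whole steps before the size factors, pseudocounts of 0.1 and 10, no floor and a floor of 250, fold thresholds of 1.5 and 4, random lists matched in 10 bins or unmatched, lists without Id2 and without members shared with another list, the table without repeated, predicted or unnamed genes, and the authors' own log2 column. A log2 ratio or list median was counted as moved when it differed by over 0.1, a percentile when it differed by over 5 points or crossed the 1st or 99th percentile, and a count when it differed by over 1.5 times.

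The percentile and the 2-fold rule were tested on simulated data for this comparison with 12679 genes. Of 200 unchanged lists of 16 members, 1.0% came out above the 99th and 2.0% below the 1st percentile. Of 200 lists with each member shifted by 0.5 on the log2 scale, 99.5% came out above the 99th percentile. Members of these simulated lists were drawn at random. The shares therefore do not cover smaller lists or lists whose members vary together. Of 200 genes changed 4-fold, 98.0% were found by the 2-fold rule. A change of that size lies well beyond the threshold, so a high share was nearly set in advance. Unchanged genes kept the spread of the observed ratios, and the share of them that passed the rule was not computed. The 98.0% therefore does not tell how many genes counted as 2-fold apart were changed. Transcript GC content, length, exon structure and gene class came from GENCODE M21 by gene symbol (14068 of 14398 symbols matched); it rests on another genome build than mm9, so no coordinates are given. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.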

Results

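RNA sequencing libraries were compared from 46C cells, a mouse embryonic stem cell line that carries a GFP reporter in the neural gene Sox1. The cells were grown on gelatin-coated plates in serum medium with leukemia inhibitory factor (LIF), which sustains self-renewal of mouse embryonic stem cells. One culture carried an empty vector and served as the control, and the other overexpressed ID2, a helix-loop-helix protein without a DNA-binding domain that dimerizes with E proteins and keeps them off DNA. Each group had 1 library. No difference below has a replicate check, an error or a test of its own, and "higher" and "lower" refer to the ID2 library against the control library. Values are the authors' normalized values, the depth behind them is unknown, and ratios are on the scale of log2(value + 1).

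Id2 stood at 324 in the control library and at 26225 in the ID2 library, an 80.6-fold difference (log2 ratio 6.33), in the direction that the labels give. The authors' deposited table lists Id2 at 80.8-fold with an adjusted p of 4.27e-77. Transcripts from the vector were counted only as far as they match the annotated mouse gene. The other members of the family were also higher, with Id3 and Id4 at levels near the floor, where ratios spread most. Among genes of the same level bin, the log2 ratios of Id1, Id3 and Id4 lay at percentiles 97.0, 83.6 and 84.9. Id1, a direct target of bone morphogenetic protein (BMP) signaling, stood at 834 and 1351 (0.69), Id3 at 57.7 and 90.4 (0.64), and Id4 at 60.7 and 98.5 (0.69). The median of the 4 genes, which includes the overexpressed one, was 0.69 and lay at percentile 99.4 of random lists, a position that the overexpression itself helps to set. Without Id2 the other 3 genes lay at percentile 97.1 (median 0.69), and with random lists also matched on exon structure the 4 genes lay at percentile 98.9; both alternatives were chosen after seeing the data.

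Of 12679 genes above the floor, 321 (2.53%) were at least 2-fold higher and 236 (1.86%) at least 2-fold lower in the ID2 library. Predicted or unnamed genes made up 55 of the former and 63 of the latter. The excess of higher genes lay mostly in coding genes with at least 80% of the transcript in 1 exon, a class chosen after values were seen, where 113 of 1494 were higher and 22 lower; among the other 10013 coding genes 155 were higher and 143 lower. The spread of ratios narrowed with level. Among genes with means from 50 to 257, the 5th and 95th percentiles of the log2 ratio were −1.07 and 1.18, and 219 genes were at least 2-fold higher and 186 lower. Among genes with means above 1927, those percentiles were −0.39 and 0.46, with 8 genes higher and 5 lower. Without a floor 551 genes were higher and 470 lower, and with a floor of 250 these counts were 105 and 53.

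**Figure D1:**
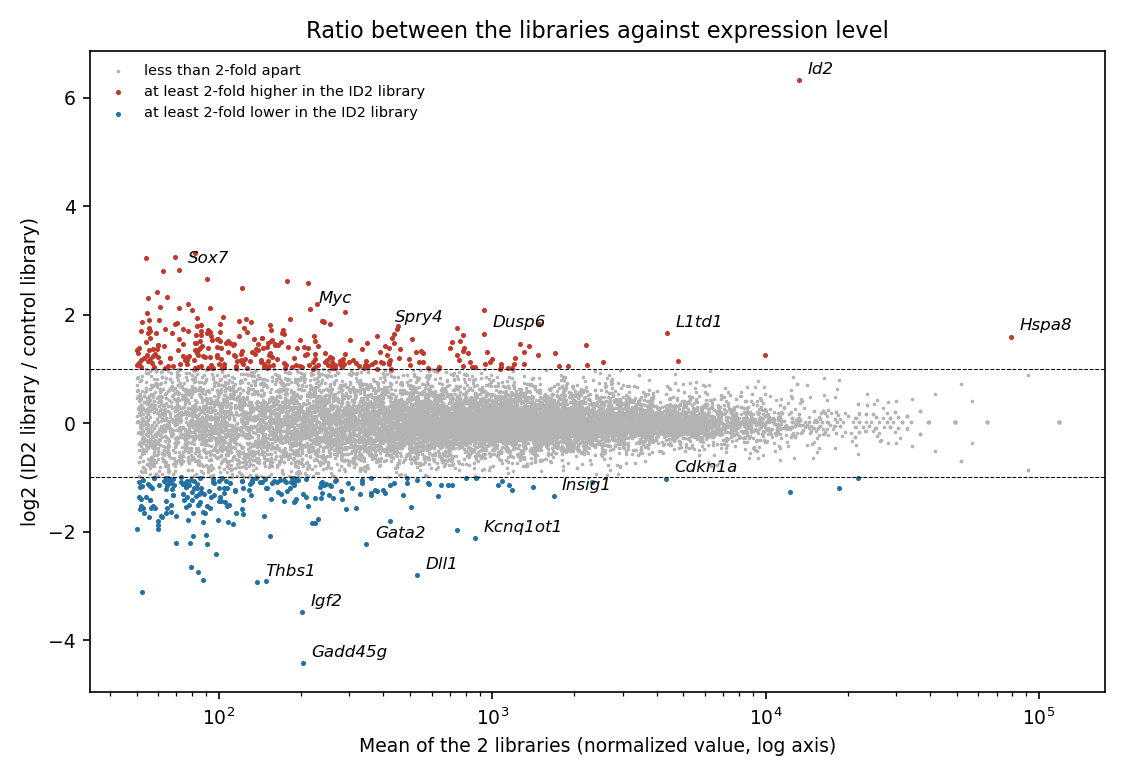
Log2 ratio of the ID2 to the control library (vertical axis) against the mean normalized value of both libraries (horizontal log axis) for the 12679 genes above the floor, 1 point per gene, with dashed lines at 2-fold. Id2 stands at 6.33, Gadd45g at −4.43, and 321 red and 236 blue points lie at least 2-fold higher or lower, most of them at low means.

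After Id2, the genes with the largest positive ratios were Xkr6 (15.9 in the control and 148 in the ID2 library, 8.79-fold), Fadd, an adaptor of death receptors (13.9 and 125), Sox7, a transcription factor of extraembryonic endoderm and endothelium (16.9 and 127), and Fancf, a member of the Fanconi anemia core complex (14.9 and 111). The zinc finger genes Zfp819 (6.34-fold), Zfp768 (6.04-fold) and Zfp319 (4.62-fold) were also among the 15 highest, as were Dolk (6.20-fold), which makes dolichyl phosphate for protein glycosylation, and Lrrc14 (5.65-fold). The remaining genes of the 15 were Ano1 (5.37-fold), Ifitm5 (20.9 and 109), Spsb4 (4.94-fold), Kctd21 (4.62-fold) and Gpr135 (4.43-fold). The control value of 12 of these 15 genes was under 50, where ratios spread most.

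Gadd45g, a growth arrest and DNA damage gene, had the largest negative ratio, with 388 in the control and 17.1 in the ID2 library (21.5-fold lower). Igf2, an imprinted growth factor, stood at 370 and 32.2 (11.2-fold lower), and Thbs1, an extracellular matrix glycoprotein, at 245 and 31.2 (7.65-fold lower). Dll1, a ligand of Notch receptors, stood at 930 and 133 (6.97-fold lower), and Gata2, a hematopoietic and trophoblast transcription factor, at 572 and 122 (4.68-fold lower). Crabp2, which carries retinoic acid, stood at 165 and 30.1, and Tagln, an actin-binding protein of smooth muscle, at 251 and 58.3. Kcnq1ot1, an imprinted antisense RNA, stood at 1405 and 322, and Rab3il1 at 1186 and 301. The other genes of the 15 lowest were Tmem59l (7.41-fold lower), Hist3h2ba (6.66-fold), Lipg (4.67-fold), Klk1 (4.64-fold), H2-Q2 (4.63-fold) and Anxa11os (4.25-fold). The ID2 value of 10 of the 15 was under 50. Because the libraries do not keep strand, reads of Kcnq1ot1 and Anxa11os cannot be told apart from those of overlapping genes on the other strand, and Klk1, H2-Q2 and the zinc finger genes have close paralogs with which reads may be shared.

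The authors' deposited table gives 26 genes an adjusted p under 0.05, of which 17 were higher and 9 lower in the ID2 library, and 554 of 14398 genes an unadjusted p under 0.05. Of the 30 genes with the largest ratios, 8 were among the 26. In the authors' deposited table Gadd45g and Dll1 each had an adjusted p of 3.05e-06, Kcnq1ot1 5.40e-05, Igf2 4.95e-04, Rab3il1 8.68e-04, Gata2 0.0125 and Zfp768 0.0266. Further genes of the 26, named here because of the authors' deposited table and so after their values were seen, included Txnip, an inhibitor of thioredoxin (17350 and 7242), Ldhb, a lactate dehydrogenase subunit (25972 and 11309), Jam2, a junctional adhesion molecule (5856 and 14012), Tenm4 (1187 and 3226), Zfhx2 (653 and 2313), Ppp1r10 (354 and 1505) and Cited2 (739 and 1999). Each pair gives the control value first.

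Pluripotency genes stood higher in the ID2 library. Of 19 naive-state genes above the floor, 14 were higher and 5 lower, with a median of 0.36 that lay above all 10000 random lists; none was 2-fold apart. Zfp42 stood at 9009 and 16218 (0.85), Nr0b1 at 931 and 1694 (0.86), Gbx2 at 331 and 560 (0.75) and Klf5 at 4586 and 7418 (0.69). Dppa3, the 1 listed gene under the floor, was lower (47.8 and 20.1, −1.21). Without members shared with other lists, the median was 0.22 at percentile 99.9. Of 16 genes of general pluripotency, 13 were higher, 2 lower and 1 equal, with a median of 0.25 at percentile 99.97. L1td1, an RNA-binding protein of pluripotent cells, stood at 2095 and 6636 (1.66; adjusted p 1.51e-05 in the authors' deposited table), and Dppa2 at 615 and 1355 (1.14). Foxd3 stood at 428 and 828 (0.95). Of the core factors, Pou5f1 stood at 12770 and 13619 (0.09), Sox2 at 11692 and 15076 (0.37) and Nanog at 14938 and 17563 (0.23).

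Markers of the formative and primed states had a median of −0.14 (4 of 11 higher, percentile 15.8) and a mean of 0.17, so that the sign differed between the summaries. Dusp6 (1.65), Otx2 (0.68) and Sall2 (0.65) were higher, and Dnmt3a was lower (−0.25). Targets of LIF and STAT3 had a median of 0.09 (9 of 18 higher, percentile 89.2) and a mean of −0.06. In that list Myc stood at 80.6 and 350 (2.10), Sgk1 at 4243 and 8320 (0.97) and Cish at 97.5 and 169 (0.79), while Gadd45g was the lowest.

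Genes that respond to fibroblast growth factor (FGF) and ERK signaling were higher, with 12 of 16 members higher and a median of 0.50 above all 10000 random lists. Spry4, a feedback inhibitor of the pathway, stood at 340 and 1152 (1.76), Dusp6, an ERK phosphatase, at 450 and 1415 (1.65), and Dusp5 at 55.7 and 161 (1.51); the authors' deposited table gives Spry4 and Dusp6 an adjusted p of 0.00671 each. Egr1, an immediate early gene, stood at 162 and 357 (1.13), and Fos, another, at 215 and 102 (−1.06). The other lower members, chosen after their values were seen, were Dusp4 (−0.81) and Spry1 (−0.32), which are also feedback inhibitors, and Fosl1 (−0.04).

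Notch pathway genes were lower at the median (−0.39, 5 of 8 lower, percentile 0.16). The ligands Dll1 (−2.80) and Jag1 (597 and 277, −1.10) and the target Hey1 (114 and 56.3, −1.01) were at least 2-fold lower. Dll3 stood at −0.58. The other members were chosen after their values were seen. The target Hes1 (2178 and 2305, 0.08) and the receptors Notch1 (0.13) and Notch3 (0.27) were higher, and Dtx1 was lower (−0.19). With a floor of 250, the median was −0.0545 at percentile 31.9, so this list's position depended on its low members.

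**Figure D2:**
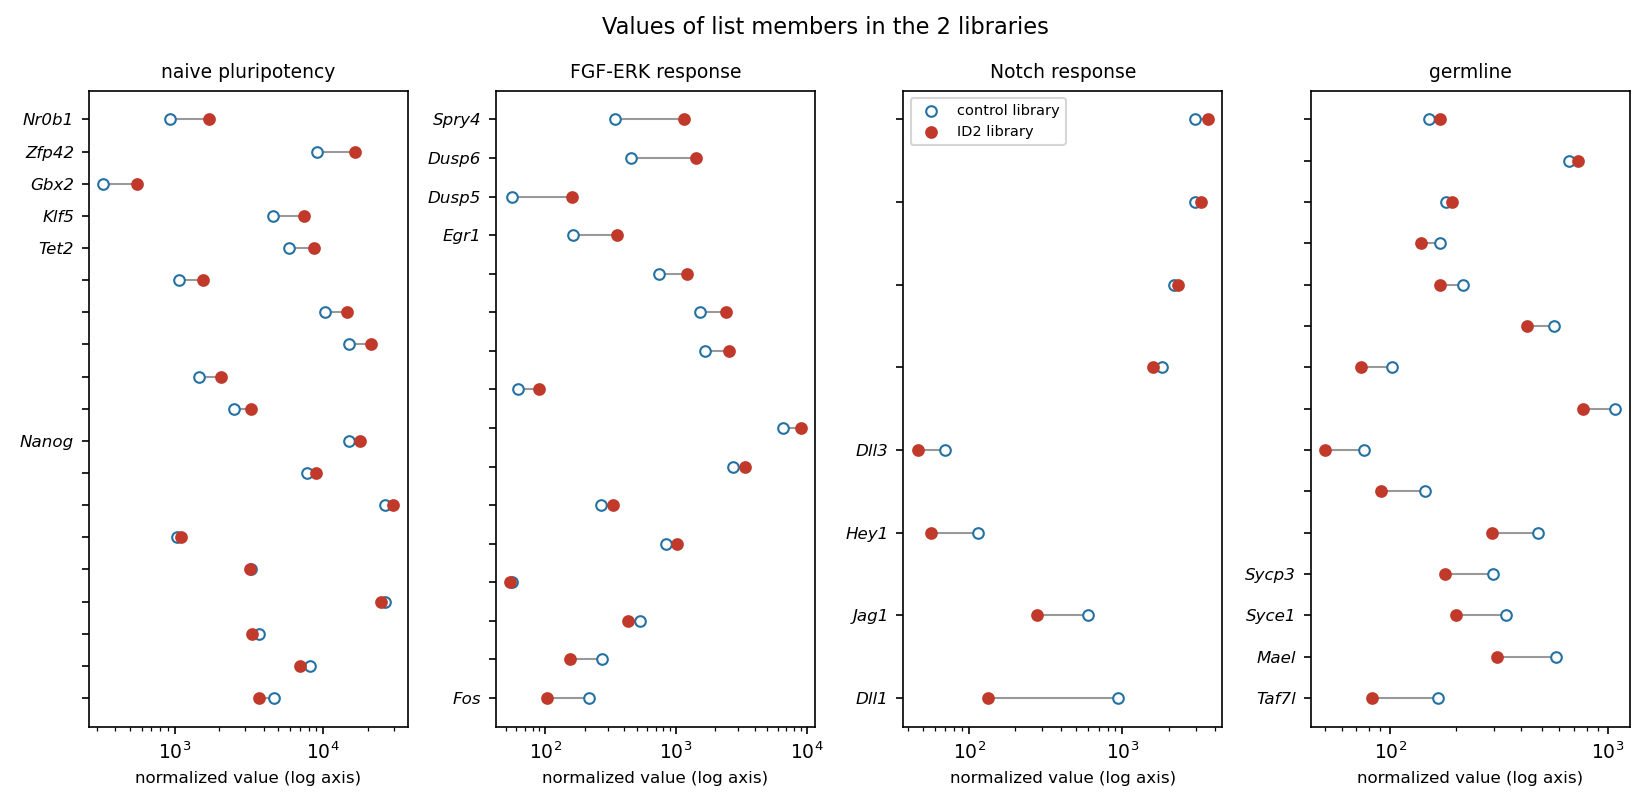
Normalized values (horizontal log axes) of the members above the floor of 4 gene lists. Open circles give the control library and filled circles the ID2 library. Each line is 1 gene, ordered by log2 ratio, and genes picked by the naming rule carry their names. For germline genes, 12 of 15 filled circles lie left of the open ones, and in the naive list 14 of 19 lie right of them.

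All 16 genes above the floor of cholesterol synthesis and uptake were lower in the ID2 library, with a median of −0.55 below all 10000 random lists. Insig1, a sterol-responsive regulator, stood at 2406 and 949 (−1.34, adjusted p 0.0194 in the authors' deposited table). Cyp51 stood at 1779 and 1083 (−0.72) and Hmgcs1 at 7641 and 4683 (−0.71). Insig1 was the 1 member that was at least 2-fold lower.

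Genes of epithelial adhesion and mesenchymal transition had a median of −0.60, below all 10000 random lists, with 12 of 15 lower, 2 higher and 1 equal. Both epithelial and mesenchymal genes stand in this list. The epithelial genes Esrp1, a splicing regulator (171 and 74.4, −1.19), and Cldn7, a claudin (482 and 237, −1.02), were lower. Mesenchymal genes went both ways: Snai3 was lower (−1.19) and Zeb1 higher (499 and 866, 0.80), and of those chosen after their values were seen, Twist1 (−0.63) and Snai1 (−0.48) were lower and Vim (0.49) higher. E-cadherin (Cdh1, 11448 and 7310, −0.65), chosen after its values were seen, was also lower. Extracellular matrix and cytoskeleton genes had a median of −0.37 at percentile 0.05, with 13 of 16 lower and 4 at least 2-fold lower. Thbs1 (−2.93), Tagln (−2.09) and Col1a1, a type I collagen (339 and 139, −1.28), were among the lowest. With a floor of 250, the median was −0.24 at percentile 1.3. Fn1 belongs to both lists and stood at the shared highest value in both libraries, so its log2 ratio of 0.01 was set by that ceiling. Markers of fibroblasts and feeder cells were lower in the same library, with a median of −0.53 over the 4 of 15 listed genes above the floor (3 lower, percentile 1.08): Col1a1, Thy1 (−0.67) and Pdgfrb (−0.38) were lower and Loxl1 higher (0.45). The 2 listed genes under the floor, Col1a2 (39.8 and 7.03) and Tnc (28.9 and 7.03), were also lower. This percentile lay between 0.02 and 5.49 under 12 alternatives and below 1 in 7 of them.

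Germline genes were lower, with a median of −0.50 at percentile 0.07 and 12 of 15 lower. Taf7l stood at 165 and 82.4 (−0.99), Mael, of the piRNA pathway, at 579 and 312 (−0.89), and the synaptonemal complex genes Syce1 and Sycp3 at −0.76 and −0.72. With a floor of 250 the median was −0.60.

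**Figure D3:**
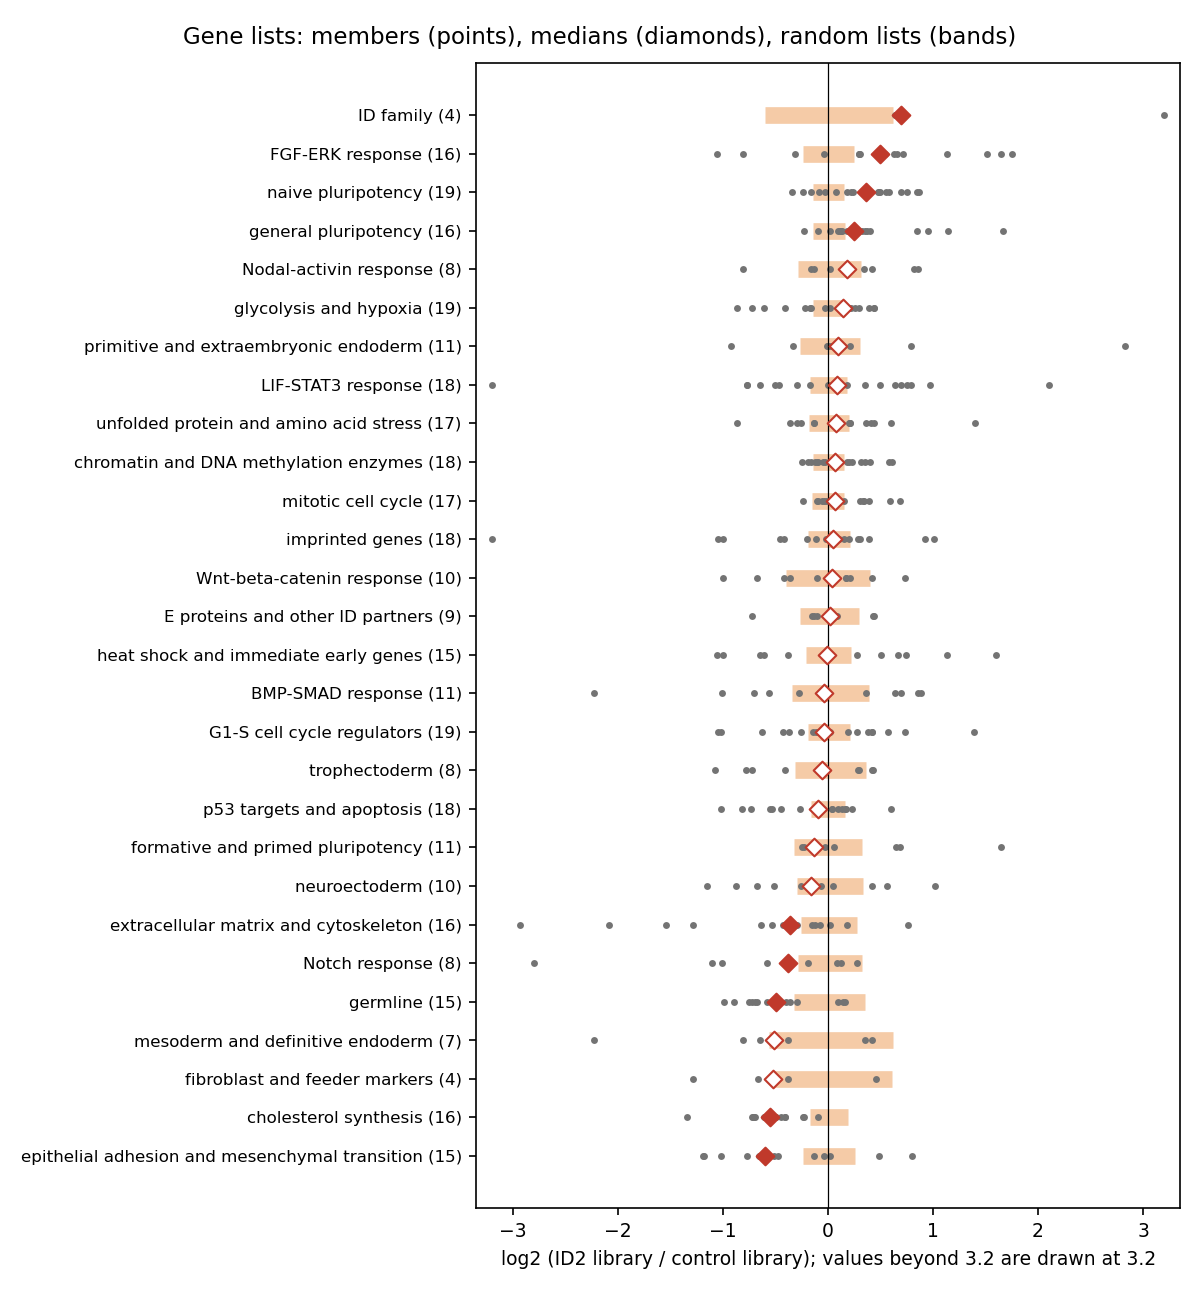
Log2 ratios of the members (gray points) and medians (diamonds, filled where the median lies outside the 1st to 99th percentile) of 28 gene lists, with the number of members above the floor in parentheses; orange bands span the 1st to 99th percentile of the medians of 10000 matched random lists. Filled diamonds lie right of their band for 4 lists, the ID family with its overexpressed member among them, and left of it for 5.

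Medians of other lineages lay between the 1st and 99th percentiles of random lists. Neuroectoderm genes had a median of −0.16 (6 of 10 lower, percentile 10.4), with Sox1, the locus of the reporter in these cells, at 386 and 782 (1.02), and Sox11 (−1.16), Nes (−0.88) and Neurod1 (−0.68) lower. Mesoderm and definitive endoderm genes had a median of −0.52 (5 of 7 lower, percentile 1.45), with Gata2 (−2.23), Fgf8 (−0.81), Cxcr4 (−0.65) and Mesp2 (−0.52) the lowest. Primitive and extraembryonic endoderm genes had a median of 0.10 (percentile 79.3), with Sox7 (2.83) and Hnf4a (0.79) higher and Gata4 (−0.93) and Lamb1 (−0.33) lower. Trophectoderm genes had a median of −0.06 (percentile 31.5), with Krt19 (−1.08), Tfap2c (−0.78) and Ascl2 (−0.72) lower and Tead4 (0.43) higher. Of 22 genes of the two-cell-like state, Sp110 alone was above the floor (−0.09).

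Partners of ID proteins, the E proteins among them, showed 4 members higher, 4 lower and 1 equal (median 0.01, percentile 56.8, mean −0.01). Ascl2 had the largest ratio (−0.72, lower), with Tcf15 (0.43) and Tcf4 (0.42) higher and Elk1 (−0.15) lower. The BMP and SMAD list had a median of −0.04 (percentile 41.3), with Fst (0.88) and Smad7 (0.86) higher and Gata2 and Hey1 lower. Nodal and activin targets had a median of 0.18 (4 higher, 3 lower and 1 equal, percentile 91.5), with Smad7, Lefty2 (0.82) and Pmepa1 (0.42) higher and Fgf8 lower (83.6 and 47.2, −0.81). Wnt targets had a median of 0.03 (percentile 58.0) and a mean of −0.09, with Ccnd2 (0.73) higher and Notum (247 and 123), Nkd1 (−0.68) and Axin2 (−0.42) lower.

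Regulators of the transition from G1 to S phase had a median of −0.04 (percentile 30.6) and a mean of 0.01. The activator E2f3 was higher (386 and 1015, 1.39), and the inhibitors Cdkn1a (5806 and 2860, −1.02) and Cdkn1c (453 and 218, −1.05) were lower. Mitotic genes had a median of 0.06 (percentile 85.1), with Cenpf (0.68), Cenpe (0.59), Aurka (0.39) and Plk1 (0.34) higher. For p53 targets and apoptosis genes the median was −0.09 (percentile 7.57), with Cdkn1a, Bbc3 (−0.82) and Pmaip1 (−0.73) lower and Sesn2 (0.60) higher. Unfolded protein and amino acid stress genes had a median of 0.07 (percentile 83.7), with Chac1 (231 and 609, 1.40) and Atf4 (0.43) higher and Ddit3 (−0.87) lower. Heat shock and immediate early genes had a median of −0.01 (percentile 43.5) and a mean of 0.08. Hspa8 stood at 39235 and 118714 (1.60; adjusted p 3.05e-06 in the authors' deposited table), where the ID2 value is the shared ceiling, and Hspa1a, which has a near-identical copy, at 117 and 58.3.

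Genes of glycolysis and hypoxia had a median of 0.14 (percentile 98.3) and a mean of −0.02, with Ldha (0.44) higher and Bnip3 (−0.87), Ndrg1 (−0.73) and P4ha1 (−0.61) lower. Imprinted genes had a median of 0.04 (percentile 70.9) and a mean of −0.18, since Igf2 (−3.48), Cdkn1c and Nnat (135 and 67.3) were far lower and Mirg higher (253 and 508). Chromatin and DNA methylation enzymes had a median of 0.07 (percentile 86.9), with Tet3 (0.60), Tet2 (0.58), Trim28 (0.40) and Jarid2 (0.35) higher. Of the 17 genes in the list of histones without poly(A) tails, Hist1h1c alone was above the floor (713 and 346, −1.04). None of the 15 mitochondrially encoded genes was listed in the table. Across all lists, 14 of 341 members above the floor (4.11%) were at least 2-fold higher and 21 (6.16%) at least 2-fold lower, beside 2.53% and 1.86% of all genes above the floor.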

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

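The alternatives without genes at the highest value, without Id2 alone and with random lists matched on exon structure were chosen after seeing the data. Of 1407 recomputed values, 1290 stayed within the tolerances, 117 moved and 0 reversed. Some alternatives could hardly move a ratio past the tolerance of 0.1. The scaling changed a median ratio of 0.9984 to 1, and the whole steps shifted log2 ratios by −0.0140. The count of 1290 is therefore not a measure of stability. The Id2 log2 ratio stayed between 6.29 and 6.34 under the alternative scalings, pseudocounts and the authors' own column. Without a floor, 551 genes were at least 2-fold higher and 470 lower, and 9 lists lay below the 1st percentile. With a floor of 250, 105 genes were higher and 53 lower, and 9 list members were at least 2-fold lower. Of the 30 genes with the largest ratios, 5 were left. These counts could only fall, because fewer genes entered, but the genes that left were mostly those whose ratios spread most. Genes with means from 50 to 257 made up 3170 of 12679. They held 219 of the 321 higher and 186 of the 236 lower genes. The lists below the 1st percentile fell to 3, since the Notch and extracellular matrix lists no longer lay there. In the same setting the medians were 0.63 for FGF and ERK, −0.0545 for Notch (percentile 31.9), −0.60 for germline and −0.24 for extracellular matrix (percentile 1.3). With a threshold of 1.5-fold, 1014 genes were higher and 835 lower, with 45 and 63 list members; with 4-fold, 23 and 18 genes and 3 and 6 list members, as the thresholds themselves set. Without Id2 and shared members the naive median was 0.22, and with random lists matched on exon structure the ID family lay at percentile 98.9; the cause was not tested. Without Id2 alone the ID family lay at percentile 97.1. Its median was 0.69 with and without Id2, and the random lists set against it were smaller too. Of 615 recomputed ratios of named genes, 31 moved, each with a pseudocount of 10, which shrinks ratios of low genes. The naive, general pluripotency, FGF and ERK, germline, cholesterol and epithelial lists stayed beyond the same percentile in every alternative run. Leaving out a library was not possible with 1 per group. No paired analysis was possible because each group had 1 library. Depth is unknown, so counting error at low values cannot be given.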

Other observations

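All groups and tests in this part were chosen after values had been seen, except the counts of GC and length deciles. Genes with zinc finger names formed a large group that stood higher in the ID2 library: of 370 above the floor, 279 were higher, 87 lower and 4 equal, with a median log2 ratio of 0.27, and 47 were at least 2-fold higher against 1 lower. Zfp768 (59.7 and 366), Zfp819 (23.9 and 157) and Zfp319 (80.6 and 376) belong to it. Many are paralogs with shared sequence, so single members are uncertain. Many also belong to the class described below, coding genes with at least 80% of the transcript in 1 exon. That class held 1494 genes with zinc finger genes and 1289 without them. Random lists for the zinc finger group were not matched on exon structure, so the 2 patterns are not separate findings. Proteasome subunits were also higher (29 of 38, median 0.14, percentile 99.85). Cytosolic ribosomal protein genes (12 of 85 higher, 54 lower and 19 equal, median −0.07, below all 1000 random lists) and subunits of the respiratory chain and ATP synthase (23 of 88 higher, median −0.09, percentile 0.4) were slightly lower. Genes for mitochondrial ribosomal proteins split into 36 higher and 40 lower.

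Noncoding classes went both ways. Antisense genes had a median of −0.24 (68 of 109 lower), unconfirmed transcripts (TEC) of −0.44 (50 of 70 lower), sense intronic genes of −0.70 (11 of 14 lower) and processed pseudogenes of −0.13 (194 of 307 lower), each below all of its random lists. Since the libraries do not keep strand, reads of antisense genes cannot be told apart from those of overlapping genes on the other strand. Long intergenic RNAs had a median of 0.10 (84 of 160 higher, percentile 98.8), and small nucleolar RNAs one of −0.25 (12 of 20 lower, percentile 5.38).

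Coding genes with at least 80% of the transcript in 1 exon were higher in the ID2 library (911 of 1494, median 0.13, 113 at least 2-fold higher and 22 lower), against a median of −0.01 for 10013 other coding genes; this class was picked after exon number, coding exon number and other shares had been tried, and the medians were 0.03, 0.07 and 0.19 at shares of 50%, 70% and 90%. A trend with transcript length is argued against by the class lying above all 1000 random lists matched on level and length (percentile 100), and the zinc finger family alone by a median of 0.091 without it, above all 1000 random lists. Genomic DNA or unspliced RNA in the ID2 library would raise sense intronic and TEC genes, whose median was −0.484. The class is not sharply bounded, since coding genes with at most 2 exons but under 80% in 1 exon also had a median of 0.09 (percentile 99.7). An effect of ID2 cannot be told apart from any other difference between the cultures or library preparations with 1 library per group, so a class effect of ID2 remains a hypothesis.

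Values came in groups of 10 that were the same in both libraries, as ranking within 10 bins of genes would give, and GC content and transcript length are candidate sources of such bins. The count written down beforehand was distinct deciles per tie group. It was 6.66 for GC content and 6.68 for length, under the bound of 7.5, which by that rule spoke against both. In the 60 highest groups, where the next test (chosen afterwards) found GC content, it was still 6.81 and 6.59. This count could therefore not separate GC content from length, and no conclusion is drawn from it. Read as places within those 60 groups, a range picked after 400 groups had been tried, 533 of 533 genes had the same place in both libraries (2 places with equal values merged), and place explained 74.5% of the variance of GC rank, against at most 4.01% in 1000 random orders. The share was 70.7% over 20 groups, 76.1% over 100, 37.3% over 200 and 8.51% over 400, with the same place for 169 of 169, 876 of 891, 1507 of 1832 and 2161 of 3731 genes, and the cause of this fall was not tested. In the 60 highest groups, place explained 4.61% of the variance of length rank left after GC content (16.9% before). Bins of GC content may therefore have been used. For those 60 groups, bins of length are argued against as the source of place. Length was not read over other ranges, where the share for GC content fell as low as 8.51%. No biological explanation was tested.

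At the ceiling, 8 genes stood at the shared highest value in both libraries, Eef1a1, Fn1, Gapdh, Hsp90ab1, Npm1, Pabpc1, Rpl4 and Rps2, so their log2 ratio of 0.01 carries no comparison. Atp5b was 1.85-fold higher, and Rps3 and Rps24 were 1.81-fold lower, by exchange between the highest group of 10 and the next. The step between these groups is 1.83-fold whatever the genes, so these ratios may reflect an exchange of ranks of any size (1.831). Hspa8 moved by 3 groups of 10, which argues against a single exchange of the first ranks. Its 3.03-fold ratio was still set by the steps between those groups (1.831, 1.308 and 1.251), whatever the gene. It also ends at the ceiling, so its size is not a measured change. No biological explanation was tested.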
